A study of Mus musculus with 3 samples.

How the data were processed

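The series holds ChIP-seq of 2 histone marks, H3K27ac and H3K27me3, in the urogenital sinus of wild-type mouse embryos at E18.5, with 1 library each of H3K27ac in males, H3K27ac in females and H3K27me3 in males (3 samples). These 3 samples were not analysed here. The series also holds CTCF ChIP-seq that the submitters mapped and called again from earlier public reads: 1 mouse list at E10.5, whose sample abbreviation is not explained in the sources used here, and 4 lists from wild-type zebrafish embryos, 2 at 24 h after fertilisation (hpf) and 2 at 48 hpf. CTCF is a zinc-finger protein that binds DNA at sites where chromatin loops stop. All 5 lists were used.

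Per the submitters' processing notes, adapters and low-quality bases were trimmed with cutadapt 4.1 (quality 30, minimum length 15), and reads were mapped with Bowtie2 2.4.5 to mm39 for mouse and to danRer11 without alternative contigs for zebrafish. Alignments with a mapping quality above 30 were kept with SAMtools 1.16.1. Peaks were called with MACS2 2.2.7.1, with summits split within regions and, for single-read libraries, reads extended to 200 bp. The notes tie 1 library to each list and name no control library, no genome size and no setting for duplicate reads. They also tie the lists labelled 48 hpf to different source records in their sample table and in their file table, so these lists are called "labelled 48 hpf" at first use and their stage rests on the label alone. The record of 24 hpf replicate 1 was numbered apart from those of the other 3 zebrafish lists, so it may come from a separate deposit. With 1 list in it, such a batch cannot be told apart from that list.

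Each list gives, per summit, a region, a display score, a fold enrichment, a −log10 p and a −log10 q. The deposited score was not used. The fold enrichment is the authors' ratio of the read pileup to the local background at the summit, with 1 added to each. Where the background is low, as in the zebrafish lists, this ratio therefore also rises with depth. The deposited −log10 values are the authors' MACS2 p-values and q-values. These are values of single peaks, and they served to describe, rank or filter peaks within a list. The exception is the lower fold over both replicates of a stage. Rows with the same region were joined, with the summit of highest −log10 q kept.

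The total number of reads per library is not given in the sources used here. The pileup (fragments over the summit) and the local background were therefore solved for each region from the fold enrichment and the −log10 p, under the Poisson score that MACS2 uses. Between 99.7% and 100% of regions per list gave a solution, and 100% of the solved pileups were whole numbers within 0.02. On simulated data with known pileups, of about 5000 regions per list, 99.7% to 99.9% of pileups were recovered. The 0.1 percentile of the local background served as the background pileup of a list, which scales with the number and length of its fragments. It was 0.489 in 24 hpf replicate 1, 0.0938 in 24 hpf replicate 2, 0.195 in 48 hpf replicate 1, 0.173 in 48 hpf replicate 2 and 9.34 in the mouse list. The backgrounds depend on a genome size that is not given, so they were compared within zebrafish only.

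Zebrafish regions of the 4 lists were linked where they overlapped by at least 1 bp. Each pair of lists was compared by the Jaccard index (regions in both lists as a percent of regions in either), with an exact Clopper-Pearson 95% binomial interval, and by the share of each list overlapped by the other, set beside 100 circular shifts along each sequence. Such intervals cover counting error only, and regions are not independent. The mean Jaccard index of the pairs within a stage minus that of the pairs across stages was compared by an exact one-sided permutation test over the 3 splits of the 4 lists into 2 and 2, whose smallest p is 0.333. A region was called stage-restricted when both lists of a stage held it and neither list of the other stage did. Nothing in the labels says that the replicates are separate clutches, so the spread between them may be technical.

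Regions are named by a rule fixed before the data were examined: the 10 regions with the highest fold in the mouse list, the 10 zebrafish regions in all 4 lists with the best lowest rank by fold, and the 10 stage-restricted regions per stage with the highest lower fold over both replicates. Coordinates are 1-based. The alternatives fixed at the same time were stricter −log10 q minimums of 5 and 10, equal numbers of strongest peaks, the 10000 strongest peaks by −log10 q, a reciprocal overlap of 50%, summits within 100 bp, assembled chromosomes only, each replicate left out, and the replicate number as a block. The analyses of chromosomes, spacing, fold quartiles and pileups, the difference between the stage-restricted numbers, and the thinning of lists to 1 background were added after the data were seen. For thinning, each pileup was drawn from a binomial distribution with the ratio of backgrounds as its probability, over 20 draws, and regions were kept whose −log10 p stayed at or above the lowest value of the list thinned to (3.25 where all lists were thinned), so a thinned number of regions is a lower bound. Chromosome spans run to the last region of any list of the species.

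No genome or annotation of mm39 or danRer11 was used here. Gene annotation of the regions, CTCF motifs and their orientation, the density of regions over the HoxD cluster and the gene lists fixed before the data were examined were therefore not analysed here, and no gene list could be tested. Regions are given by position only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.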

Results

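The study concerns the regulatory landscapes around the HoxD genes and their evolution, and earlier public CTCF reads from mouse and zebrafish embryos were analysed again for it. CTCF regions were available as 5 lists, each called from 1 library. The mouse E10.5 list held 106750 regions with 110455 summits. The zebrafish lists held 78999 regions in 24 hpf replicate 1, 40667 in 24 hpf replicate 2, 44760 in the list labelled 48 hpf replicate 1 and 40349 in the list labelled 48 hpf replicate 2. Each list reached down to the same significance, with a largest q of 0.0487 to 0.0499. The regions had a median width of 379 bp in mouse and of 280 to 406 bp in zebrafish.

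The depth behind the zebrafish lists differed. The background pileup of 24 hpf replicate 1 was 5.21 times that of 24 hpf replicate 2, 2.51 times that of 48 hpf replicate 1 and 2.83 times that of 48 hpf replicate 2. The median region rested on 13 overlapping fragments in 24 hpf replicate 1, on 6 in 24 hpf replicate 2, on 9 in 48 hpf replicate 1 and on 10 in 48 hpf replicate 2. In 24 hpf replicate 2, 48.7% of regions rested on 5 fragments or fewer, against 9.63% in 24 hpf replicate 1. In the mouse list the median was 72 fragments.

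The first question was which CTCF regions recur in zebrafish embryos. The 4 lists joined into 103327 regions, of which 22400 (21.7%) were in all 4 lists and 57826 (56.0%) in a single list. 24 hpf replicate 1 alone gave 36501 of the regions found once. Regions with a high fold recurred in most lists. In the strongest quartile by fold, 95.4% of the regions of 24 hpf replicate 2 (95% interval 94.96 to 95.79) were in all 4 lists, as were 95.5% for 48 hpf replicate 1 (95.1 to 95.9) and 96.3% for 48 hpf replicate 2 (95.9 to 96.7). The share was 64.5% (63.9 to 65.2) in 24 hpf replicate 1, whose longer list gave a larger quartile. It held 19717 regions, 12722 of them in all 4 lists. The strongest quartiles of the other lists held 10008 to 11090 regions, with 9608 to 10596 in all 4 lists. The lower share is therefore not a lower number of recurrent strong regions. In the weakest quartile the shares were 5.47%, 11.4%, 8.07% and 13.5% in the 4 lists, in the order 24 hpf replicates 1 and 2 and 48 hpf replicates 1 and 2. Of the 1000 strongest regions of each list, between 966 and 999 were in all 4 lists.

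**Figure D1:**
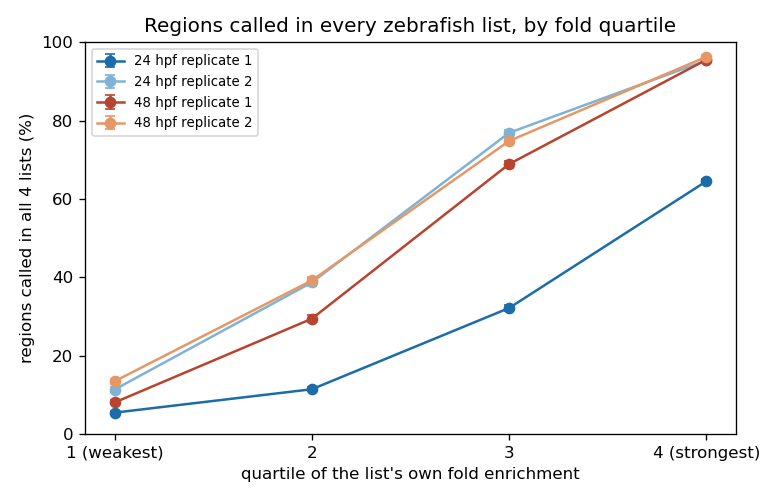
Share of regions called in all 4 zebrafish lists (y axis, percent) by quartile of the list's own fold enrichment (x axis), 1 line per list with exact 95% binomial intervals. The strongest quartile reached 95.4% to 96.3% in 3 lists and 64.5% in 24 hpf replicate 1, and the weakest stayed between 5.47% and 13.5%. Quartiles differ in size with the length of the list (strongest: 19717 regions in 24 hpf replicate 1, 10008 to 11090 in the others).

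The recurrent region with the best lowest rank lay on danRer11 chromosome 22, 605888 to 606423, with folds of 39.7 and 37.3 at 24 hpf and 33.7 and 34.9 at 48 hpf (replicates 1 and 2 in each case). The next lay on chromosome 10, 28117483 to 28118107, with folds of 38.8, 32.1, 32.4 and 31.2. The region on chromosome 6, 41535675 to 41536215, had folds of 38.8, 27.8, 36.6 and 36.1. The other 7 of the 10 named regions were on chromosomes 23, 10, 21, 25, 6 and 17, 2 of them on chromosome 23, at 7488238 to 7488833 and at 13958044 to 13958633. All 10 ranked within the first 195 of the recurrent regions in every list.

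The second question was how far replicates of a stage shared their regions. The 48 hpf pair shared 29797 of the 54593 regions in either list, a Jaccard index of 54.6% (95% interval 54.2 to 55.0). The 24 hpf pair shared 29164 of 89992, or 32.4% (32.1 to 32.7). Between the 48 hpf replicates, 66.7% of the regions of replicate 1 were in replicate 2 and 73.9% of those of replicate 2 were in replicate 1. Between the 24 hpf replicates the shares were 36.8% of replicate 1 and 72.3% of replicate 2, so the low index of this pair came with lists of unequal length. Circularly shifted regions gave a mean overlap of 2.35% for the 48 hpf pair and 2.39% for the 24 hpf pair.

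The third question was whether CTCF regions differed between 24 and 48 hpf. The 4 pairs across stages had Jaccard indices of 38.4% and 38.2% where they held 24 hpf replicate 1, and of 43.8% and 46.5% where they held 24 hpf replicate 2. The 24 hpf pair was thus lower than each of the 4 pairs across stages, and the 48 hpf pair was higher than each. The mean within stages exceeded the mean across stages by 1.74 percentage points (exact permutation p = 0.333, one-sided, over 3 splits, the smallest p this design allows). The split by replicate number gave 0.205 points and the crossed split gave −1.95. With 2 lists per stage no p under 0.05 can be reached, and the 24 hpf pair had a lower Jaccard index than any pair of lists from different stages. The order differed by the share of 24 hpf replicate 2 found in each other list: 72.3% lay in the longer list of 24 hpf replicate 1, against 63.3% and 62.7% in the 48 hpf lists. That longer list, however, held more of 48 hpf replicate 1 (77.0%) and of 48 hpf replicate 2 (82.0%) than of 24 hpf replicate 2. With lists of such unequal length, these shares do not decide on the stage.

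**Figure D2:**
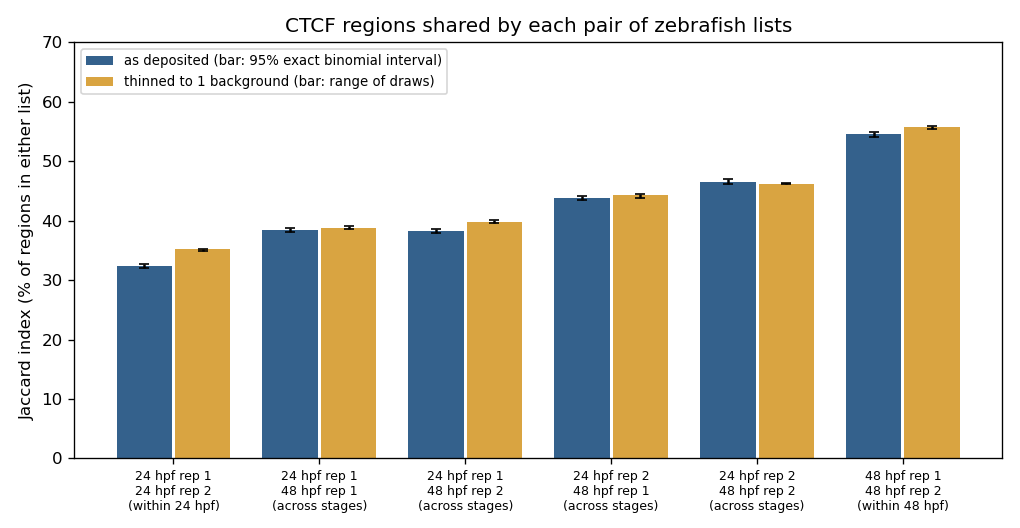
Jaccard index of each pair of zebrafish lists (y axis, percent of the regions in either list) as deposited, with exact 95% binomial intervals, and after all lists were thinned to 1 background pileup, with the mean and range of 20 draws. The 24 hpf pair was the lowest of the 6 (32.4% as deposited, 35.2% thinned) and the 48 hpf pair the highest (54.6% and 55.7%).

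Stage-restricted regions were few and mostly weak. Of the 29164 regions in both 24 hpf lists, 3105 (10.6%) were in neither 48 hpf list, and of the 29797 regions in both 48 hpf lists, 1138 (3.82%) were in neither 24 hpf list. The lower fold over both replicates had a median of 3.57 in the 24 hpf-restricted regions, against 6.12 in the other regions of both 24 hpf lists, and of 4.203 against 7.65 at 48 hpf. Of the regions with a lower fold of at least 10, 8 of 4875 at 24 hpf (0.164%) and 16 of 10015 at 48 hpf (0.160%) were stage-restricted. The fold rises with depth, which differed between the lists, so these numbers do not compare the stages. Grouping the lists by replicate number instead of stage gave 4423 and 554 restricted regions, and the crossed grouping gave 3364 and 599. As deposited, the 24 hpf number thus lay below the numbers that both other groupings gave for the side with 24 hpf replicate 1. With all lists thinned to 1 background it lay above them, at 2462 against 1847.5 by replicate number and 1774.5 crossed (medians of 20 draws). The 24 hpf lists were then the longest (means of 44962 and 40604 regions, against 34590 and 33631 at 48 hpf). Only the grouping by stage sets the longest lists against the shortest, which favours the 24 hpf number. The order of the 24 hpf number after thinning therefore decides nothing about the stage. The 48 hpf number lay above those of the side without 24 hpf replicate 1 in both other groupings. It did so as deposited (1138 against 554 and 599) and after thinning (1773.5 against 1451.5 and 1257), where the 48 hpf lists were the shortest. With 3 groupings, this does not test the stage. The excess of 24 hpf over 48 hpf regions turned to an excess of 48 hpf regions with equal numbers of strongest peaks, at 1553 against 2916. It also turned at a −log10 q of at least 10 (a difference of −540) and with the 10000 strongest peaks (−792). A reciprocal overlap of 50% turned it too (−114). It stayed positive at a −log10 q of at least 5 (112) and with summits within 100 bp (337). It also did so with assembled chromosomes only (1934) and after thinning (688.5). Thus 4 of 8 alternatives turned it. Without 48 hpf replicate 1 or 2 it was −689 or −3915, and without 24 hpf replicate 1 or 2 it was 5681 or 37623. With 1 list of a stage left, only that list has to hold a region, which raises the stage's number. These signs therefore say little about the stages. Leaving out 1 list moved the 24 hpf number to between 4816 and 39606 and the 48 hpf number to between 1983 and 8731.

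The 24 hpf-restricted region with the highest lower fold was on chromosome 3, 61527344 to 61527856, with folds of 18.9 and 13.2. It was followed by chromosome 15, 4598912 to 4599574, with 13.0 and 23.8, and chromosome 22, 30773250 to 30773893, with 17.4 and 11.6. The 48 hpf-restricted region with the highest lower fold was on chromosome 5, 11417702 to 11418101, with folds of 21.1 and 19.5. It was followed by chromosome 23, 43307038 to 43307436, with 16.2 and 17.2, and chromosome 15, 24676335 to 24676564, with 14.5 and 18.8. The lower folds of the 10 named regions per stage ran from 9.48 to 13.2 at 24 hpf and from 11.1 to 19.5 at 48 hpf. Each is a region that was not called at the other stage, which is not a test of a lower level there.

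Along the zebrafish chromosomes, chromosome 4 had the fewest CTCF regions per Mb in each list. Recurrent regions lay at 9.64 per Mb on chromosome 4 and at 14.9 to 18.9 per Mb on the other chromosomes. The gap lay between 30 and 70 Mb, bounds chosen after the positions were seen, where 38 recurrent regions gave 0.95 per Mb against 16.9 per Mb on the other chromosomes. The rest of chromosome 4 held 18.8 per Mb. In the single lists the interval held 321 regions in 24 hpf replicate 1, 142 in 24 hpf replicate 2, and 117 in each 48 hpf list, which was between 7.39 and 11.5 times fewer per Mb than on the other chromosomes, and between 8.90 and 24.4 times fewer at a −log10 q of at least 10. The 10 longest distances between neighbouring recurrent regions were all on chromosome 4, the longest being 2.74 Mb.

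**Figure D3:**
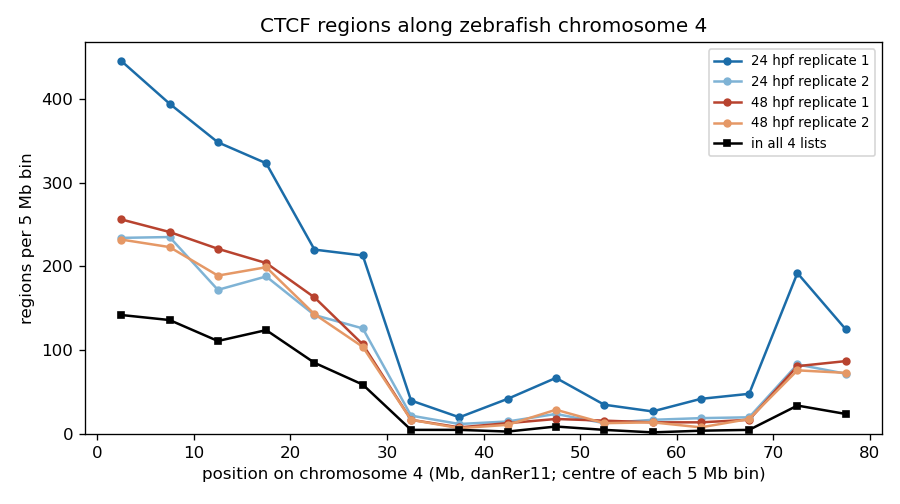
Number of CTCF regions per 5 Mb bin (y axis) along danRer11 chromosome 4 (x axis, Mb), for each zebrafish list and for regions in all 4 lists. Bins between 30 and 70 Mb held 2 to 9 recurrent regions each, against 59 to 142 in the bins before 30 Mb.

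Chromosome ends held more regions than chromosome interiors. The first and last 1 Mb of the 25 chromosomes held 31.6 recurrent regions per Mb against 15.9 per Mb in between, a ratio of 1.99, and 50 of 50 ends lay above their own chromosome's interior. In the 4 lists the ratio was 1.67 to 1.80, and 49 or 50 of 50 ends lay above the interior (exact two-sided binomial test, largest adjusted p = 9.1e-14 over 9 tests). Both ends of a chromosome were compared with the same interior, and the lists share regions, so neither ends nor tests are independent. The far end of each chromosome was also set by its last region.

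In mouse, the strongest CTCF region by fold was on mm39 chromosome 3, 61175856 to 61176714, with a fold of 24.1 and a pileup of 321 fragments. It was followed by chromosome 17, 34084385 to 34084845, with a fold of 23.5, chromosome 13, 14063889 to 14064588, with 22.4, and chromosome 16, 93423636 to 93424108, with 22.3. The region on chromosome 11, 94520195 to 94520717, had a fold of 22.0 and the highest −log10 q of the list, 338.3. It was the only 1 of the 10 that was also among the 10 highest by −log10 q. The other 5 of the 10, on chromosomes X, 14, 4, 11 and 1, had folds between 21.3 and 21.9. Of the 10, those on chromosomes 17, 16, 4 and 1 ranked only 6622, 9331, 6364 and 7588 by −log10 q. Those on chromosomes 17 and 16 had a local background of 9.34, the background pileup of the list. No mouse region exceeded a pileup of 399, just below the 400 that 1 read per position and strand allows with fragments of 200 bp, the shortest region of that list, and 11.5% of regions lay at 300 or more. No such limit showed in the zebrafish lists. Their highest pileups were 3292 and 1318 at 24 hpf and 712 and 602 at 48 hpf, with shortest regions of 162 to 209 bp. Whether zebrafish pileups hold duplicate reads is open.

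Mouse chromosome 11 held the most CTCF regions per Mb, 58.9, and chromosome 14 the fewest among the autosomes, 34.5, with an autosomal median of 42.0. Chromosome X held 2722 regions, or 16.1 per Mb, which was 2.61 times fewer than the autosomal median. Its median local background was 9.90 against 13.2 on the autosomes, and its median pileup was 71 against 72. The 90th percentile of pileup was 250.9 on X against an autosomal median of 311, and lay below that of every autosome. Chromosome Y held 48 regions. The densest windows of 100 kb were on chromosome 11, from 3100001 to 3200000, and on chromosome 5, from 15000001 to 15100000, with 27 regions each.

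**Figure D4:**
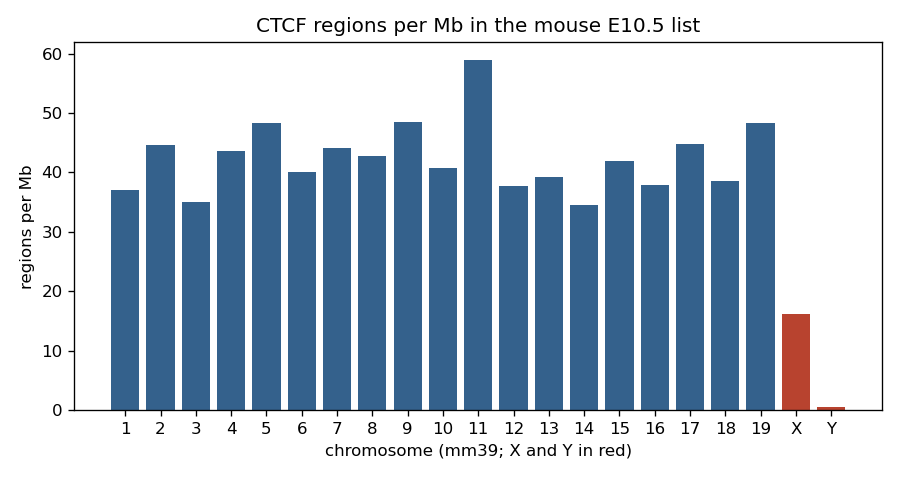
CTCF regions per Mb (y axis) on each mouse chromosome (x axis, mm39) in the E10.5 list, 1 bar per chromosome. Chromosome 11 was highest at 58.9 per Mb and chromosome X, at 16.1, lay below every autosome (lowest 34.5).

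Set side by side, without a test, the mouse list held 39.2 regions per Mb and the recurrent zebrafish regions 16.4 per Mb. The zebrafish lists held 57.8, 29.8, 32.8 and 29.6 per Mb. The median distance between neighbouring regions was 11845 bp in mouse, where random placement on the same chromosomes gave 16186 bp. Distances under 10 kb made up 43.9% of all in mouse against 34.9% at random. Distances above 100 kb were also more frequent, at 3.53% against 1.91%. Mouse regions were thus spaced less evenly than randomly placed ones. No genome was used, so sequence where no read could be placed was not left out of the random placement. The difference therefore does not show that CTCF sites cluster. Recurrent zebrafish regions had a median distance of 34286 bp against 41681 bp at random, and 15.9% of distances were under 10 kb against 15.4%. The single zebrafish lists also had shorter median distances than random placement (10964 against 11859 bp and 21258 against 23060 bp at 24 hpf, 18835 against 20941 bp and 20356 against 23225 bp at 48 hpf, replicates 1 and 2). Their shares under 10 kb went both ways, with 24.7% of distances under 10 kb against 26.01% at random in 24 hpf replicate 2, 46.2% against 44.3% in 24 hpf replicate 1, 26.8% against 25.9% in 48 hpf replicate 2, and 28.5% in 48 hpf replicate 1, within the highest random value of 28.6%. The lists differ in depth, so the densities of the species are not a comparison of how many sites CTCF occupies.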

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

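Thinning, the difference between the stage-restricted numbers, and the chromosome ratios with their −log10 q minimum of 10 were chosen after the data were seen. The 24 hpf pair stayed the lowest and the 48 hpf pair the highest of the 6 in all 9 settings run, and the gap by stage stayed positive and above both other splits, from 1.72 to 8.59 points, in a design that cannot give a p below 0.333. The causes of the shifts below were not tested, except that stricter minimums and shorter lists hold fewer regions by construction.

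Jaccard indices of the 24 hpf and 48 hpf pairs were 29.9% and 70.8% at a −log10 q of at least 5, 25.3% and 74.9% at 10, 39.7% and 57.2% with equal numbers of strongest peaks, 36.6% and 74.2% with the 10000 strongest, 23.0% and 47.9% with a reciprocal overlap of 50%, 23.1% and 45.6% with summits within 100 bp, and 35.2% and 55.7% after thinning.

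The 24 hpf-restricted regions numbered 970 at a −log10 q of at least 5, 403 at 10, 1553 with equal numbers, 522 with the 10000 strongest and 1922 with a reciprocal overlap. The 48 hpf-restricted regions numbered 2916 with equal numbers, 2036 with a reciprocal overlap, 2293 with summits within 100 bp and 1773.5 (median of draws) after thinning. The difference, 24 hpf minus 48 hpf, turned from 1967 to −540 at a −log10 q of at least 10, −1363 with equal numbers, −792 with the 10000 strongest and −114 with a reciprocal overlap. These were 4 of 8 alternatives. In the others the difference ran from 112 at a −log10 q of at least 5 to 1934 with assembled chromosomes only. Without 1 replicate it ran from −3915 (without 48 hpf replicate 2) to 37623 (without 24 hpf replicate 2), and was −689 without 48 hpf replicate 1. Without 1 replicate the 24 hpf number ran from 4816 to 39606 and the 48 hpf number from 1983 to 8731, since fewer lists have to hold or lack a region. The replicate block gave the same 3105 and 1138 regions by construction. The labels' numbers were not shown to pair the lists.

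At a −log10 q of at least 10 the lists held 34697 (24 hpf replicate 1), 9562 (24 hpf replicate 2), 17015 (48 hpf replicate 1) and 17141 (48 hpf replicate 2) regions. There the chromosome 4 density ratios kept their direction but fell from 0.135 to 0.112, 0.116 to 0.0595, 0.0869 to 0.0410 and 0.0965 to 0.0446 in the same order of lists. The chromosome-end ratios rose from between 1.67 and 1.80 to between 2.17 and 2.63 (24 hpf replicate 2), and the mouse X ratio went from 0.383 to 0.422. Without 1 list neither the replicate overlap nor the gap has a value at that stage. The alternatives for annotation, motifs, motif orientation, HoxD density and gene lists were not run. With few fragments per region, a region missing from a zebrafish list may lie under its detection limit. Thinned to the background of 24 hpf replicate 2, the 24 hpf pair stood at 35.2%. Thinning brings the lists to 1 depth but does not remove that limit, so the value does not decide whether regions were missed.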

Other observations

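The prediction on depth for the number of regions in 24 hpf replicate 1 and the one on mapping for chromosome 4 were written before their results were seen. The other tests in this part were chosen after related values had been seen.

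24 hpf replicate 1 held 1.76 to 1.96 times as many regions as each other zebrafish list. Thinned to the mean background of the 48 hpf lists, it kept 57235 regions (57104 to 57413 over 20 draws), 1.34 times their mean number of 42555, above the bound set in advance for depth as the whole cause. Thinned to the background of 24 hpf replicate 2, it kept 44955, or 1.11 times the number in that list, so depth as a part of the difference stays open. The stage stays open too: with all lists thinned to 1 background, both 24 hpf lists (44962 and 40604 regions) held more than both 48 hpf lists (34590 and 33631), but 24 hpf replicate 2 set the background and was not itself thinned, while the 48 hpf numbers are lower bounds, so its 1.19 times the 48 hpf mean comes partly from the construction and decides nothing. A separate deposit of this library or better enrichment may add to the difference, and neither was tested.

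The 4 zebrafish lists grouped by stage at 48 hpf and not at 24 hpf. With all lists thinned to 1 background, the 48 hpf pair lay 9.46 points above the highest pair across stages, which leaves the stage open there. The 24 hpf pair differed from the lowest pair across stages by −3.61 points, which argues against the stage for that pair. It was the lowest of the 6 in 20 of 20 draws, against the prediction for depth. The draws, however, resample the same called regions and leave lists of unequal length. They also do not remove the detection limit, so depth stays open. 24 hpf replicate 1 standing apart is a candidate explanation for the 24 hpf pair: each pair with it lay below each pair among the other 3 lists, with a gap of 4.49 points. The splits of 4 lists are too few for a share under 0.05 (1 of 3 reached the real gap of 1.74 points, and the highest other gap was 0.205). After thinning the gap by stage was 3.16 points against −1.22 and −1.95. Restricted regions then numbered 2462 and 1773.5 by stage, 1847.5 and 1451.5 by replicate number, and 1774.5 and 1257 crossed (side with 24 hpf replicate 1 first). Thinning left the 24 hpf lists the longest, which favours the 24 hpf number, so that number decides nothing about the stage. The 48 hpf number is not favoured in this way and was the highest of the 3 for the side without 24 hpf replicate 1. With 3 splits, this does not test the stage. Whether a batch, the embryos or the label sets 24 hpf replicate 1 apart stays open, because only 1 list has a record numbered apart.

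Few regions lay between 30 and 70 Mb on zebrafish chromosome 4. If repeats there lost reads to the mapping quality filter, more of the regions called inside would sit at the lowest background of their list. The share of regions within 1% of that background was higher inside than on the other chromosomes in all 4 lists. The difference was 18.47 to 39.06 points (median 26.96), as predicted for lost reads. No control library is named, however, so the local background may come from the ChIP reads themselves. It would then be low wherever few regions lie nearby, whatever the cause, so this test cannot decide on lost reads. For a detection limit at low depth the values go both ways, and it stays open: the density ratio of the deepest list was 1.164 times that of the shallowest as deposited (95% interval 0.952 to 1.43), but 1.89 times (1.13 to 3.35) at a −log10 q of at least 10, while both 48 hpf lists, which are deeper than the shallowest, had lower ratios than it (0.0869 and 0.0965 against 0.116 as deposited, 0.0410 and 0.0446 against 0.0595 at that minimum), so the ratios did not follow depth. A low background from chromatin state would look alike, and no biological explanation was tested.

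The lists also held regions on the mitochondrial genome. There were 4 in the mouse list, with a median fold of 1.92, 5 in 48 hpf replicate 1 (2.54), 4 in 48 hpf replicate 2 (3.49), 1 in 24 hpf replicate 2 and 0 in 24 hpf replicate 1.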
